A study of Mus musculus with 8 samples.

How the data were processed

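Poly(A) RNA was sequenced from 8 samples of mouse bone marrow-derived macrophages (BMDMs), cells grown from bone marrow for 7 days with 10 ng/ml of the growth factor M-CSF and 10% serum. Per the labels, the mice carried a wildtype (WT) or a conditional knockout (cKO) genotype for PTIP, the protein of Paxip1, and the cells received LPS, a bacterial cell wall component, at 100 ng/ml for 0 or 6 h. Each of the 4 groups held 2 samples. The series text calls them biological replicates. The labels do not say whether a replicate number marks a mouse, so p-values measure the spread between these samples.

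Per the labels' protocols, RNA was extracted with Trizol, selected on oligo-dT beads, fragmented and copied with random primers, and the libraries were amplified for 15 PCR cycles. Such a library covers whole transcripts and counts PCR copies together with original fragments. The submitters' processing notes name CASAVA, HISAT2 2.1.0, featureCounts, DESeq2 and the mouse genome GRCm38, without roles or settings. The annotation, the strand setting and the treatment of reads that match several genes are not given in the sources used here. Genes with near-identical copies, overlapping genes and antisense partners are therefore uncertain.

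The authors deposited 1 table of 55226 genes. The authors named it as rlog output, and its values are log2 expression values after a regularised log transformation that pulls genes with few reads toward their mean. Per the file headers, the same table holds the authors' own log2 fold changes, p-values and adjusted p-values for 4 comparisons. No read counts were used here, so the depth of each sample is unknown and no interval from counts can be given. Values ran from -2.31 to 19.31, and 26727 genes were listed at 0 in every sample. Differences on the rlog scale understate the change of low genes. Gene names were matched to the GENCODE M21 annotation of GRCm38 for position, transcript length and GC content. A value was found for 11423 of the 11543 genes tested. The names of 24 genes in the table look like calendar dates, 13 of them among the tested genes.

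Genes with a mean rlog of at least 3 over the 8 samples were tested, which left 11543. A linear model with 4 group means was fitted to all 8 samples with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend of the variance on the mean). The model had 4 residual degrees of freedom, with 4.4 more borrowed across genes. The 7 comparisons were LPS against 0 h in each genotype, cKO against WT at each time, their interaction and both averaged effects. Adjusted p-values are Benjamini-Hochberg values over the tested genes, with a threshold of 0.05. Log2 differences are given with their standard error (SE) from this model.

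Before the data were examined, 38 gene lists were written from textbook knowledge, none from this study. The 34 lists with at least 5 tested genes entered limma's camera test with a preset correlation of 0.01 between genes. Adjusted p-values cover 170 tests, the 34 lists in 5 comparisons. The tests were repeated with an estimated correlation and with fry. With an estimated correlation none of the 55 list calls held, and the smallest adjusted p was 0.398. That version also missed the cytokine list when it was shifted by 0.5 log2 units in simulated values (camera adjusted p = 0.149). With the preset correlation its adjusted p was 2.19e-14, and 1 of 167 null tests passed. The simulated genes were independent, so the preset correlation itself was not tested. Nor can it tell a loss of power from a real correlation between genes. The estimated correlation was 0.70 for interferon-stimulated genes, 0.73 for mitochondrially encoded transcripts and 0.47 for cholesterol synthesis. It was 0.004 for ribosomal protein genes and -0.003 for DNA repair genes. Where it exceeds 0.01, p-values with the preset correlation may be too small. A loss with an estimated correlation does not by itself decide against a list, and a preset call does not by itself decide for it. For counts per list, calls were made over all tested genes and again adjusted over the list alone. LPS-responsive genes were those called for the LPS effect averaged over genotypes with an absolute log2 change of at least 1. In this balanced design that average is uncorrelated with the interaction. Their camera p-values were adjusted over 4 tests, 2 sets in 2 comparisons; this adjustment was added after seeing the data.

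Named genes followed a rule fixed in advance. Paxip1 and the measured members of the PTIP complex list come first. For each comparison the 8 largest rises and the 8 largest falls past the threshold were taken, if the 2 groups did not overlap. For the interaction, both cKO changes by replicate number had to lie on the same side of both WT changes. Genes known only by a clone, Rik or Gm name and annotated pseudogenes were left out. For each list described, up to 2 of the largest rises and up to 2 of the largest falls past the threshold were taken, or the 2 smallest p where none passed. Tnf, Il6, Il1b, Il12b, Nos2, Ifnb1, Cxcl10, Ccl5, Il10 and Arg1 are named in any comparison as indicator genes. Values of some genes that the rule would name are not reported here.

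The code was tested on simulated values with the real gene means and spreads. The simulated genes were independent and, apart from the planted changes, did not differ between groups. Recovery and false calls may differ in the real data, where genes are correlated. For cKO against WT after LPS, 64% of 100 genes changed by 1 log2 unit and 99% of 100 changed by 2 were recovered among 11543 genes, with 10 false calls. For the interaction the shares were 25% and 89%, with 7 false calls. Alternatives chosen in advance were other filters, variance models, scalings and samples in the fit, a replicate block, a size threshold, other list tests and leaving out each sample. A correction for GC content and transcript length and a count of calls in the authors' deposited table were added after seeing the data. That count took in all 55226 genes of the table, also those not tested here.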

Results

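Gene expression was measured by RNA sequencing in mouse bone marrow-derived macrophages of 2 genotypes, WT and PTIP cKO, before and 6 h after LPS. Each of the 4 groups held 2 samples. The series title names PTIP as a regulator of histone methylation and of inflammatory responses, and the design asks how its loss alters macrophages at rest and after LPS. Depth is unknown because only transformed values were used. The 2 samples of a group correlated across genes at r = 0.987 to 0.992, and genes are not independent replicates. The first principal component, with 75.3% of the variance, separated the LPS samples from the others, and the second, with 11.9%, separated the genotypes. On the second, replicate 1 also lay above replicate 2 in each of the 4 groups. The values were 23.5 and 11.5 in WT at 0 h, 25.2 and 12 in WT after LPS, -4 and -22.1 in cKO at 0 h, and -18 and -28.1 in cKO after LPS. This component therefore mixes genotype with replicate number.

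Paxip1, the gene of PTIP (chromosome 5, 27740080 to 27791691, minus strand, GRCm38), was lower in every library labelled cKO. Its rlog was 4.50 and 4.50 in WT at 0 h, 3.82 and 4.08 in WT after LPS, 2.54 and 2.48 in cKO at 0 h, and 2.54 and 2.63 in cKO after LPS. The difference between cKO and WT was -1.99 (SE 0.18, adjusted p = 0.00686) at 0 h and -1.37 (SE 0.18, adjusted p = 0.0156) after LPS. In the authors' deposited table, which is not on this shrunken scale, the log2 fold changes were -4.75 at 0 h (adjusted p = 0.00196) and -4.04 after LPS (adjusted p = 1). Which exons were deleted is not given in the labels. Of its tested partners in the histone H3K4 methyltransferase complex and in DNA repair, none passed the threshold in cKO against WT at either time with limma, and 0 at 0 h and 3 after LPS had an unadjusted p under 0.05. Adjusted over the list alone, Paxip1 was the 1 call at 0 h, and after LPS Paxip1 and Kmt2c were lower and Wdr5 was higher. At 0 h the differences were 0.67 for Ash2l, 0.09 for Dpy30, -0.12 for Kdm6a, 0.23 for Kmt2c, -0.13 for Kmt2d, 0.26 for Ncoa6, -0.21 for Rbbp5, 0.03 for Rif1, 0.41 for Trp53bp1 and -0.04 for Wdr5. After LPS they were 0.14 for Ash2l, -0.07 for Dpy30, -0.25 for Kdm6a, -0.60 for Kmt2c, 0.04 for Kmt2d, -0.12 for Ncoa6, -0.36 for Rbbp5, -0.24 for Rif1, 0.16 for Trp53bp1 and 0.46 for Wdr5. Pagr1a was below the filter on low values.

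**Figure D1:**
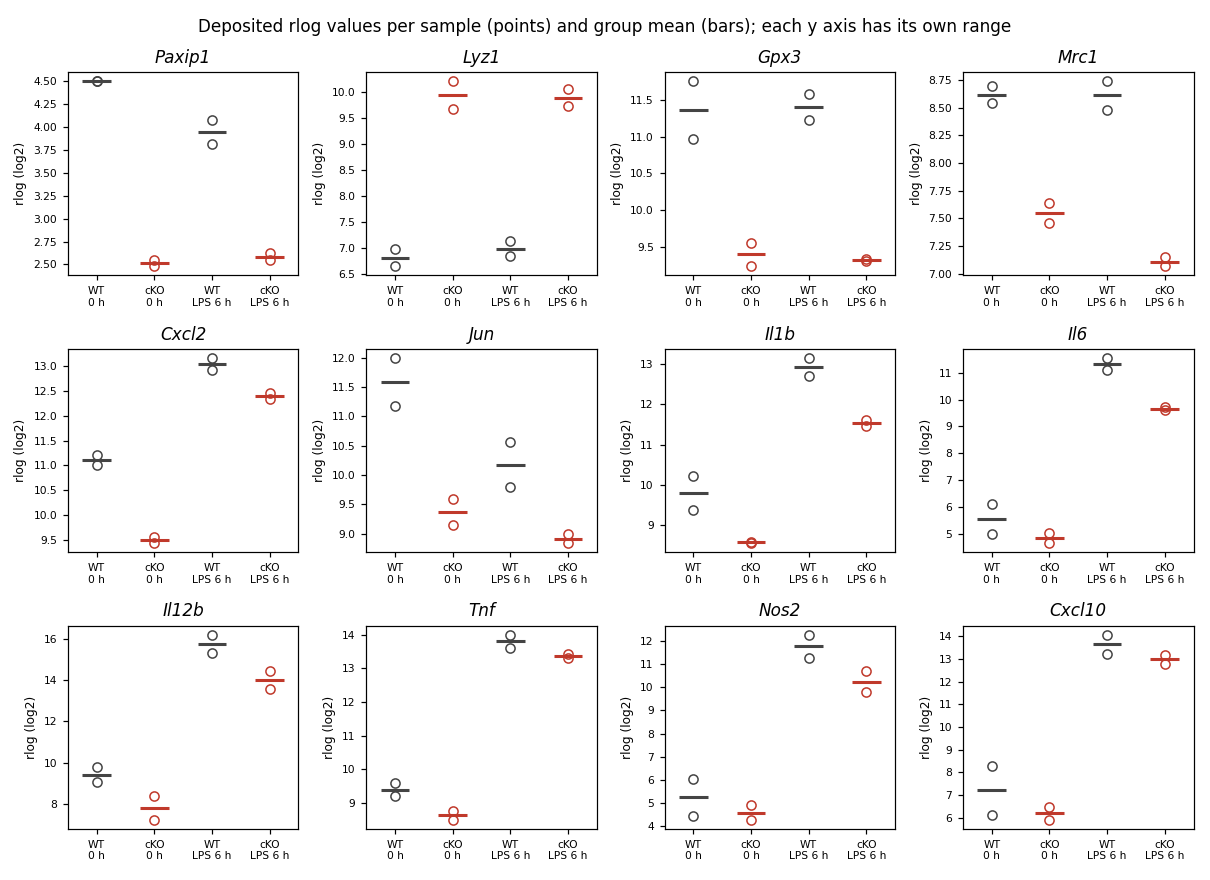
Deposited rlog values (log2, y axes with separate ranges) of 12 genes in the 4 groups (x axis); each open circle is 1 of the 2 samples and each bar the group mean. Paxip1 lies between 2.48 and 2.63 in the 4 cKO samples and between 3.82 and 4.50 in the 4 WT samples, and Lyz1 is higher in every cKO sample than in any WT sample.

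In WT macrophages LPS raised 2598 and lowered 2273 of 11543 genes. The rises with the greatest size were in Il27 (6.71, SE 0.46), a cytokine subunit, Nos2 (6.50, SE 0.55), the inducible nitric oxide synthase, and Cxcl10 (6.45, SE 0.59), an interferon-induced chemokine. Il12b rose by 6.35, Ifi205 by 5.99, Cd40, a costimulatory receptor, by 5.95, Ch25h, which makes 25-hydroxycholesterol, by 5.79, and Serpina3f by 5.78. The leading falls were in Cd300lb (-4.30, SE 0.14), Susd3 (-3.74), Tmem154 (-3.68), Sesn1 (-3.48), Zfp36l1 (-3.45), the cannabinoid receptor gene Cnr2 (-3.43), the isocitrate dehydrogenase gene Idh1 (-3.42) and Rab3il1 (-3.26). Among the other indicator genes Il6 rose by 5.76, Tnf by 4.41, Ccl5 by 4.33, Il1b by 3.14 and Il10 by 1.62, while Arg1 differed by 0.35 (adjusted p = 0.298). Ifnb1 lay below the filter, with rlog values of 1.54 and 1.60 at 0 h and 4.24 and 3.29 after LPS. The authors' deposited table called 1996 genes higher and 1410 lower, and 1833 and 1382 of these were called in the same direction here, with 0 in the opposite one. With no filter on low values Il10 did not pass (adjusted p = 0.0888).

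All 45 tested interferon-stimulated genes rose in WT (45 adjusted over the list alone), led by the guanylate-binding protein gene Gbp5 (5.55) and the GTPase gene Iigp1 (5.54). Their camera adjusted p was 3.5e-22, with an adjusted p = 0.494 with an estimated correlation. Of 39 NF-kB target genes 35 rose (36 adjusted over the list alone), with Cd69 at 5.32, and the adjusted p was 2.58e-16 (adjusted p = 0.398 with an estimated correlation). Inflammatory cytokines rose in 18 of 20 genes (18 rose and 1 fell adjusted over the list alone, adjusted p = 3.86e-10), and chemokines in 18 of 22 (18 adjusted over the list alone, adjusted p = 6.49e-07), Cxcl9 by 5.09. Both had an adjusted p = 0.398 with an estimated correlation. Antigen presentation genes rose in 16 of 25 (17 adjusted over the list alone, adjusted p = 5.48e-07), with Cd86 at 3.23, and the adjusted p was 0.398 with an estimated correlation. Of 28 negative feedback genes 18 rose and 1 fell (20 and 2 adjusted over the list alone). Il1rn, the interleukin 1 receptor antagonist, rose by 4.36, and Irak3 fell by 0.80 (adjusted p = 0.0527 after a correction for GC content and transcript length, and 0.138 with no filter on low values). The list's adjusted p was 2.39e-06 (adjusted p = 0.506 with an estimated correlation). Toll-like receptor pathway genes rose in 25 of 40 and fell in 3 (26 and 3 adjusted over the list alone), with the receptor gene Tlr3 at 3.51 and the kinase gene Mapk14 at -1.37. Their adjusted p was 0.000153 (adjusted p = 0.545 with an estimated correlation). Inflammasome genes rose in 12 of 19 and fell in 2 (12 and 3 adjusted over the list alone), with the cytokine gene Il18 at 3.31 and Nlrp1b at -1.18. Their adjusted p was 0.00308 (adjusted p = 0.398 with an estimated correlation). Adhesion and matrix genes rose in 15 of 30 and fell in 6 (16 and 7 adjusted over the list alone), with Mmp13 at 4.63 and Tgfbi at -1.37. Their adjusted p of 0.0485 (adjusted p = 0.4 with an estimated correlation) was 0.0699 without WT LPS replicate 1, 0.0503 without cKO 0 h replicate 1, 0.0508 with samples centred on their medians and 0.0938 with a minimum mean rlog of 5.

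Cholesterol synthesis genes fell in 15 of 24 (17 fell and 1 rose adjusted over the list alone), among them Dhcr7 (-2.18) and Acat2 (-1.88). The list had an adjusted p = 9.67e-05, and adjusted p = 0.745 with an estimated correlation. DNA repair genes went both ways: 10 of 25 fell, such as Chek2 (-2.35) and Xrcc6 (-2.06), and 2 rose, Atm (2.0) and Fanca (1.52), with the same counts adjusted over the list alone. The adjusted p was 0.0069 (adjusted p = 0.398 with an estimated correlation), and 0.0984 when only genes with a mean rlog of at least 5 were tested. Of 44 cell cycle genes 18 fell, led by the replication helicase gene Mcm2 (-1.68) and the nucleotide reductase gene Rrm2 (-1.52, adjusted p = 0.0886 with no filter), and 8 rose, led by Tpx2 (2.81) and Mki67 (2.04). Those counts were the same adjusted over the list alone. The list's adjusted p of 0.0229 was 0.81 with an estimated correlation; it was 0.0711 without WT 0 h replicate 1, 0.103 without WT LPS replicate 2, and 0.299 with the higher filter. Mitochondrially encoded transcripts rose in 12 of 15 (12 adjusted over the list alone), with mt-Rnr2 at 0.92 and mt-Co2 at 0.91. Quantile normalization ended these calls of mt-Rnr2 (0.11, adjusted p = 0.68) and mt-Co2 (0.57, adjusted p = 0.0787), and mt-Co2 also lost it after the correction for GC content and length (adjusted p = 0.0531) and with no filter (adjusted p = 0.0553). The list's adjusted p was 0.00189, and adjusted p = 0.81 with an estimated correlation.

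In cKO macrophages LPS raised 2260 and lowered 2015 genes. Cxcl10 (6.78, SE 0.59), Il27 (6.72, SE 0.46), Cd40 (6.28), Il12b (6.20), Serpina3f (6.03), Ifi205 (6.03), Serpina3g (5.81) and the histidine decarboxylase gene Hdc (5.71) led the rises. Susd3 (-4.20), Tcp11l2 (-3.69), Cd300lb (-3.56), Cnr2 (-3.49), Galnt9 (-3.31), Tmem154 (-3.25), Zfp36l1 (-3.21) and Klc4 (-3.11) led the falls. Nos2 rose by 5.64, Il6 by 4.80, Tnf by 4.75, Ccl5 by 4.47 and Il1b by 2.98. Il10 differed by 0.58 (adjusted p = 0.319) and Arg1 by 0.23 (adjusted p = 0.512). The count of 4275 fell to 2845 without cKO LPS replicate 1 and to 2684 without cKO LPS replicate 2.

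All 45 interferon-stimulated genes rose in cKO as well (45 adjusted over the list alone, adjusted p = 2.2e-23, and adjusted p = 0.493 with an estimated correlation). So did 34 of 39 NF-kB targets (35 adjusted over the list alone), 17 of 20 cytokines (17 adjusted over the list alone) and 16 of 22 chemokines (18 adjusted over the list alone). These lists had adjusted p-values of 5.58e-17, 3.16e-10 and 1.13e-06, and each had an adjusted p = 0.398 with an estimated correlation. The chemokine genes Ccl6 (-0.82) and Ccl25 (-0.78) fell. Antigen presentation genes rose in 16 of 25 (16 rose and 1 fell adjusted over the list alone), with Cd40 at 6.28, and the adjusted p was 7.03e-07 (adjusted p = 0.398 with an estimated correlation). Negative feedback genes rose in 17 of 28 and fell in 1 (19 and 1 adjusted over the list alone), with Il1rn at 4.15 and Nr4a1 at -1.60 (list adjusted p = 6.49e-07). The call of Nr4a1 ended with no filter (adjusted p = 0.194), without a variance trend (adjusted p = 0.0507) and with a robust fit (adjusted p = 0.0704). Toll-like receptor pathway genes rose in 20 of 40 and fell in 3 (22 and 3 adjusted over the list alone), with Tlr3 at 3.34 and Mapk14 at -0.61 (list adjusted p = 2.58e-05). Both lists had an adjusted p = 0.494 with an estimated correlation. Inflammasome genes rose in 10 of 19 and fell in 2, the same counts adjusted over the list alone, with Il18 at 2.90 (list adjusted p = 0.00558). DNA repair genes fell in 11 of 25 and rose in 2, again the same counts adjusted over the list alone, with Chek2 at -1.99 and Fanca at 1.60 (list adjusted p = 0.00429). Adhesion and matrix genes rose in 15 of 30 and fell in 3 (16 and 6 adjusted over the list alone), with Itga5 at 2.78 and Timp2 at -1.32 (list adjusted p = 0.0354). Each of these 3 lists had an adjusted p = 0.398 with an estimated correlation. The adhesion list's adjusted p was 0.0506 without WT LPS replicate 1, 0.0504 without cKO LPS replicate 1 and 0.0895 with a minimum mean rlog of 5.

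In cKO as in WT, LPS lowered genes of cholesterol synthesis and the cell cycle. Cholesterol synthesis genes fell in 13 of 24, and 2 rose, such as Srebf2 at 0.66 (14 and 3 adjusted over the list alone). The call of Srebf2 ended under quantile normalization (adjusted p = 0.0687) and with no filter (adjusted p = 0.0889). That list had an adjusted p = 0.00215 (adjusted p = 0.81 with an estimated correlation). Cell cycle genes fell in 25 of 44 and rose in 5 (26 and 5 adjusted over the list alone, adjusted p = 0.000707, and adjusted p = 0.692 with an estimated correlation). Of the 15 mitochondrially encoded transcripts 0 passed the threshold, over all genes or adjusted over the list alone, 1 had an unadjusted p under 0.05, and the list's adjusted p was 0.802. The calls of the 2 genotypes shared 1949 rises and 1575 falls, where independent lists of these sizes would share 508.7 and 396.8. There was 1 gene called in opposite directions, Fiz1 (-0.61 in WT and 0.60 in cKO), which was singled out after its values were seen. These 2 comparisons have no library in common. They share the variance estimate of each gene, so calls can coincide more often than for independent lists.

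Before LPS, 6 genes were higher and 23 lower in cKO than in WT. The 6 were Lyz1 (3.13, SE 0.22, adjusted p = 0.00392), a lysozyme gene, the RNA-binding protein gene Elavl1 (2.04, SE 0.19, adjusted p = 0.00686), the glutamate dehydrogenase gene Glud1 (1.87, SE 0.24), Dgkg (1.58), Ankrd37 (1.47, adjusted p = 0.0573 after the correction for GC content and length) and Klra3 (1.34). Lyz1 lies on chromosome 10 from 117287797 to 117292868, on the minus strand, next to its paralog Lyz2, with which it can share reads. The leading falls were in Jun (-2.22, SE 0.31, adjusted p = 0.0389), an AP-1 transcription factor, Paxip1, the glutathione peroxidase gene Gpx3 (-1.97, SE 0.25), the lectin gene Mgl2 (-1.96), Slc7a8 (-1.83), the phosphatase gene Dusp1 (-1.71), Rbp4 (-1.64) and Pmp22 (-1.64). Of the indicator genes none passed: the difference was -1.60 for Il12b, -1.23 for Il1b, -1.01 for Cxcl10, -0.77 for Tnf, -0.69 for Il6, -0.66 for Nos2, -0.54 for Ccl5, 0.06 for Il10 and 0.18 for Arg1. Passing the threshold was sensitive to single libraries, in runs that leave a lone sample in 1 group. Fewer genes passed without WT 0 h replicate 1, cKO 0 h replicate 2 or either cKO LPS library. More passed without cKO 0 h replicate 1, and most of those were higher in cKO. All 29 genes kept their direction whichever of the 4 libraries at 0 h was left out, although the same libraries chose them. A limma fit of the 4 samples at 0 h alone called 0 genes, with 1117 at an unadjusted p under 0.05. The authors' deposited table called 72 higher and 104 lower over all its genes, tested here or not. Of these, 6 and 22 were called here too. Of the 21 genes that the naming rule chose and that were called, 8 kept their call with no filter on low values and 6 without a variance trend, among them Lyz1, Elavl1 and Paxip1 in both. Quantile normalization ended the calls of Dgkg (adjusted p = 0.0599), Dusp1 (adjusted p = 0.0562) and Sdc1 (adjusted p = 0.0568). A minimum mean rlog of 5 ended those of Ankrd37 (adjusted p = 0.052), H2-T23 (adjusted p = 0.0519) and Jun (adjusted p = 0.052), and a robust fit that of Jun (adjusted p = 0.0661).

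Immediate early genes, which respond to signals within minutes, were lower as a list at 0 h in cKO, with a median of -0.88 over 21 genes. Jun and Dusp1 fell, and 10 fell adjusted over the list alone. The adjusted p was 1.07e-09, and adjusted p = 0.481 with an estimated correlation. The median was -0.56 without WT 0 h replicate 1 and -1.41 without WT 0 h replicate 2. Of 22 chemokine genes 2 fell (5 adjusted over the list alone), Cxcl1 (-1.62) and Cxcl2 (-1.60), both neutrophil attractants, with an adjusted p of 1.13e-06 (adjusted p = 0.398 with an estimated correlation). Of 20 cytokines 0 passed over all genes, 8 had an unadjusted p under 0.05 and 5 fell adjusted over the list alone (adjusted p = 1.69e-06, and adjusted p = 0.424 with an estimated correlation). Il1b (-1.23) and Tnf (-0.77) had their smallest p-values. Alternative activation genes fell in 3 of 20, Mgl2, Mrc1 (-1.07) and Tgm2 (-1.14), with 6 lower and 2 higher adjusted over the list alone. That list had an adjusted p = 0.000403 (adjusted p = 0.494 with an estimated correlation). NF-kB targets were lower as a list, with 0 of 39 called over all genes, 14 at an unadjusted p under 0.05 and 5 lower adjusted over the list alone (adjusted p = 1.13e-06, and adjusted p = 0.403 with an estimated correlation). So were antigen presentation genes (median -0.22), where H2-T23 fell by 0.93 as 1 of 25, also adjusted over the list alone (adjusted p = 2.44e-05, and adjusted p = 0.398 with an estimated correlation). Adhesion and matrix genes had 1 of 30 called, the proteoglycan gene Sdc1 (-1.47), and 7 lower adjusted over the list alone (adjusted p = 0.000549, and adjusted p = 0.398 with an estimated correlation). Negative feedback genes had 1 of 28 called, Dusp1, and 5 lower adjusted over the list alone (adjusted p = 5.97e-05, and adjusted p = 0.589 with an estimated correlation). Of 40 Toll-like receptor pathway genes 0 were called by limma over all genes, 11 had an unadjusted p under 0.05 and 2 were lower adjusted over the list alone (adjusted p = 0.000225, and adjusted p = 0.559 with an estimated correlation). Of 24 unfolded protein response genes 1 fell, the phosphatase subunit gene Ppp1r15a (-1.20), and 2 did adjusted over the list alone. That adjusted p of 0.00452 was 0.494 with an estimated correlation, 0.358 without WT 0 h replicate 2 and 0.071 without cKO 0 h replicate 1.

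The interferon-stimulated list at 0 h (0 of 45 genes called, 3 at an unadjusted p under 0.05, 1 lower adjusted over the list alone, adjusted p = 0.0284, and adjusted p = 0.924 with an estimated correlation) turned to the higher side without cKO 0 h replicate 1 (adjusted p = 0.00115), and its adjusted p was 0.152 without WT 0 h replicate 1 and 0.054 with a minimum mean rlog of 5. Ribosomal protein genes were higher as a list (median 0.13 over 34 genes, adjusted p = 0.000502, and adjusted p = 0.398 with an estimated correlation), with 0 genes called over all genes or adjusted over the list alone and 1 at an unadjusted p under 0.05.

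After LPS, 174 genes were higher and 284 lower in cKO than in WT. The authors' deposited table called 296 higher and 350 lower over all its genes, of which 145 and 204 were called here in the same direction. The leading falls were in Mmp13 (-3.19, SE 0.48, adjusted p = 0.017), a collagenase gene, the adhesion molecule gene Vcam1 (-2.57, SE 0.47), the lysophosphatidic acid receptor gene Lpar1 (-2.35), Ptgs2 (-2.29), which encodes the inducible cyclooxygenase, Thbs1 (-2.24), Ms4a6b (-2.23), U90926 (-2.12) and Gpx3 (-2.10). The leading rises were in Tysnd1 (3.46, SE 0.48, adjusted p = 0.0156), Lyz1 (2.91, SE 0.22, adjusted p = 0.00344), Clptm1 (2.75), Trp53rka (2.71), Tspan17 (2.45), Psmd3 (2.35), Trp53rkb (2.35) and Glud1 (2.33). Trp53rka and Trp53rkb are similar copies and uncertain. Tysnd1 also differed between the cKO samples at 0 h, with rlog values of 5.95 and 7.73. Il6 fell by 1.65 (SE 0.33, adjusted p = 0.0353) and Il1b by 1.39 (SE 0.26, adjusted p = 0.0294). The differences of Il12b (-1.75, adjusted p = 0.0739), Nos2 (-1.52, adjusted p = 0.151), Il10 (-0.98), Cxcl10 (-0.67), Tnf (-0.43, adjusted p = 0.226), Ccl5 (-0.40) and Arg1 (0.07) did not pass. Far fewer genes passed without either of the cKO LPS libraries or without WT LPS replicate 1, runs that leave a lone sample in 1 group. All 458 genes kept their direction whichever library was left out, although the same libraries chose them. Libraries at 0 h do not enter this difference, so leaving them out could not change it. Quantile normalization called 115 higher and 120 lower, and 123 higher and 115 lower had an absolute log2 change of at least 1. Of the 47 genes that the naming rule chose and that were called in this comparison, 24 kept their call with it, and it ended those of Il6 (adjusted p = 0.0826), Il1b (adjusted p = 0.0869), Ptgs2 (adjusted p = 0.077), Clptm1, Trp53rka and Tspan17, and of Ccl8, Cd274, Cd86, Csf3 (adjusted p = 0.061), Dusp1, Gbp5, Klf6, Mapk14 and P2rx7. With no filter on low values 11 of the 47 kept their call, among them Lyz1 and Mrc1, and Il6 (adjusted p = 0.156) and Il1b (adjusted p = 0.136) lost it. Without a variance trend 33 kept it, and Il6 (adjusted p = 0.0521) did not. The correction for GC content and length ended the calls of 8, namely Ccl8, Cd86, Clptm1, Hif1a, Mapk14, Socs1, Trp53rka and Tspan17.

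Of 20 cytokines 7 fell in cKO after LPS (13 adjusted over the list alone), led by Il6 and Csf3 (-1.63), the granulocyte growth factor. The list's adjusted p was 1.22e-07, and adjusted p = 0.398 with an estimated correlation. Of 22 chemokines 4 fell (11 adjusted over the list alone), among them Ccl8 (-1.69) and Ccl6 (-1.22), with an adjusted p of 1.13e-06 (adjusted p = 0.398 with an estimated correlation). NF-kB targets fell in 4 of 39 (13 adjusted over the list alone, adjusted p = 2.58e-05, and adjusted p = 0.49 with an estimated correlation). Antigen presentation genes fell in 2 of 25, H2-T23 (-1.22) and Cd86 (-1.28), and in 6 adjusted over the list alone, with an adjusted p of 8.2e-05 (adjusted p = 0.403 with an estimated correlation). Immediate early genes fell in 2 of 21, Dusp1 (-1.51) and Klf6 (-0.81); 12 fell and 1 rose adjusted over the list alone, and the adjusted p was 3.05e-06 (adjusted p = 0.545 with an estimated correlation). Inflammasome genes fell in 2 of 19, Il1b and the ATP receptor gene P2rx7 (-0.63), with 6 adjusted over the list alone, an adjusted p of 0.00447, and adjusted p = 0.398 with an estimated correlation. Of the interferon-stimulated genes only Gbp5 (-0.87) fell over all genes, and 0 did adjusted over the list alone; the list of 45 had a median of -0.38, an adjusted p of 2.74e-05, and adjusted p = 0.83 with an estimated correlation. Negative feedback genes fell in 3 of 28, such as Dusp1 and Cd274 (-0.91), and Socs1 (1.13) rose (4 and 1 adjusted over the list alone). That adjusted p of 0.0062 was 0.792 with an estimated correlation and 0.461 without WT LPS replicate 1. Toll-like receptor pathway genes fell in 4 of 40, among them the receptor genes Tlr1 (-1.49) and Ifnar1 (-1.06), and Mapk14 (0.79) rose. Adjusted over the list alone 9 fell and 2 rose; the adjusted p of 0.033 was 0.81 with an estimated correlation, 0.495 without WT LPS replicate 1, 0.129 without cKO LPS replicate 1 and 0.0865 with a minimum mean rlog of 5.

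Macrophage identity genes fell in 3 of 36 after LPS in cKO, among them the mannose receptor gene Mrc1, by 1.50 (SE 0.15, adjusted p = 0.00638), and Itgam (-1.11), and Lyz1 rose (8 and 2 adjusted over the list alone). Alternative activation genes fell in 2 of 20, Mgl2 (-2.08) and Mrc1 (2 fell and 1 rose adjusted over the list alone). Of 34 ribosomal protein genes 0 were called by limma, over all genes or adjusted over the list alone, and 5 had an unadjusted p under 0.05. The adjusted p-values of these lists, 0.0424, 0.0475 and 0.0475, were 0.57, 0.773 and 0.403 as adjusted p with an estimated correlation. Without WT LPS replicate 1 they were 0.235, 0.681 and 0.101. Leaving out either cKO 0 h library or cKO LPS replicate 2 also ended all 3 calls, with adjusted p-values from 0.0539 to 0.0933. Without cKO LPS replicate 1 the last 2 were 0.0534 and 0.0914, and without WT LPS replicate 2 the last was 0.0617. With a minimum mean rlog of 5 the first 2 were 0.0767 and 0.0809; with samples centred on their medians the 3 were 0.0508, 0.0568 and 0.0594, and the last was 0.146 after the correction for GC content and length.

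**Figure D2:**
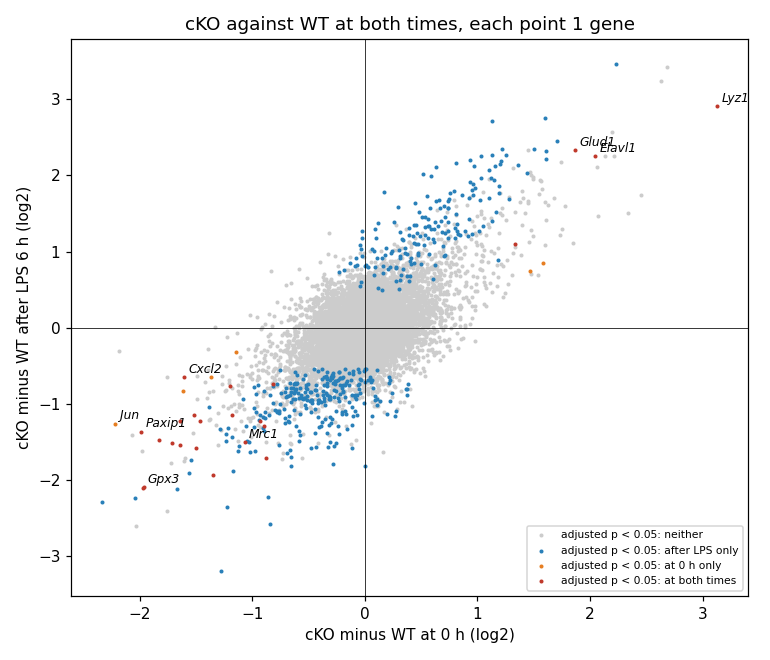
Log2 difference between cKO and WT at 0 h (x axis) and after 6 h of LPS (y axis) for 11543 genes, each a point, coloured by whether the adjusted p was below 0.05 at either time. Lyz1, Elavl1 and Glud1 lie at the upper right, and Gpx3, Paxip1 and Mrc1 at the lower left; 4 rises and 19 falls passed at both times.

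Calls in cKO against WT at both times covered 4 rises and 19 falls, where independent lists would share 0.1 and 0.6. The differences at the 2 times correlated across genes at r = 0.626 (Spearman's rho = 0.466). No library is in both comparisons, although the labels do not exclude a culture shared between times. Both comparisons use the same variance estimate per gene, so calls can coincide more often than for independent lists. Averaged over times, 332 genes were higher and 478 lower in cKO. That average takes the 4 libraries of a genotype as independent. If a mouse or culture gave both times, its p-values may be too small. The excess of falls was not stable: 393 were higher and 327 lower without cKO 0 h replicate 1, 127 and 100 at an absolute log2 change of at least 1, and 327 and 343 under quantile normalization. That count of 810 was 109 without cKO LPS replicate 2, 247 without cKO LPS replicate 1, 321 without WT 0 h replicate 1, 376 without WT LPS replicate 1 and 447 without cKO 0 h replicate 2. Marker lists of neutrophils, B cells, dendritic cells, mast cells and osteoclasts held 0 genes called in cKO against WT at either time over all genes. Adjusted over the list alone, 1 neutrophil gene was higher at each time, S100a8 (1.03 at 0 h and 0.88 after LPS), which was singled out after its values were seen. At an unadjusted p under 0.05 with limma there were 1, 0, 2, 1 and 1 genes of these lists at 0 h, and 1, 0, 1, 1 and 0 after LPS. None of these lists passed by camera at either time. The 5 neutrophil genes had a median of 0.35 at 0 h, with 4 above 0, and of 0.59 after LPS, with all 5 above 0 (adjusted p = 0.129 and 0.0719, and adjusted p = 0.494 and 0.49 with an estimated correlation). The 11 dendritic cell genes had a median of -0.20 at 0 h, with 8 below 0, and of -0.23 after LPS, with all 11 below 0 (adjusted p = 0.243 and 0.262). The medians of B cell, mast cell and osteoclast genes were -0.20, 0.20 and -0.086 at 0 h and -0.17, -0.31 and -0.082 after LPS (adjusted p = 0.352 to 0.937).

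Whether the LPS response itself differed between the genotypes was tested by the interaction, which called 0 of 11543 genes with limma. An unadjusted p under 0.05 was found for 751 genes, where 577 would be so by chance. With no filter on low values 10 genes passed. Mitochondrially encoded transcripts had a lower LPS change in cKO, with a median interaction of -0.65 over 15 genes, led by mt-Rnr2 (-1.05) and mt-Nd6 (-0.94). The list's adjusted p was 1.1e-07 (adjusted p = 0.545 with an estimated correlation, 0 genes called over all genes or adjusted over the list alone, 6 at an unadjusted p under 0.05). Of 1296 genes induced by LPS on average, the median change was 1.70 in WT and 1.50 in cKO, and the median interaction was -0.20 (quartiles -0.43 and 0.05). The camera adjusted p for this set was 5.48e-07, and adjusted p = 0.0727 with an estimated correlation. Of these genes 118 were lower and 8 higher in cKO after LPS, all among the 458 calls. Their unchanged direction with a library left out decides little, since the same libraries chose them. Far fewer passed without either cKO LPS library or without WT LPS replicate 1. The higher count was 23 without cKO 0 h replicate 2, 13 without WT 0 h replicate 2 and 2 without WT LPS replicate 2. Under quantile normalization 49 were lower and 7 higher, and the median interaction was -0.11. For these counts and median interactions, the induced and repressed sets were chosen again with a library left out or under quantile normalization. Without cKO 0 h replicate 2 the median interaction was -0.10 in the set chosen again and -0.12 over the same 1296 genes. Before LPS the median difference of the 1296 genes between cKO and WT was -0.12, and it was -0.063 without cKO 0 h replicate 1 and -0.19 without cKO 0 h replicate 2. Of 820 repressed genes the median interaction was 0.13 (adjusted p = 6.23e-05, and adjusted p = 0.0496 with an estimated correlation), with 22 higher and 5 lower in cKO after LPS. Without WT LPS replicate 1 these counts were 2 and 0, without either cKO LPS library both were 0, and without cKO 0 h replicate 1 they were 38 and 4. Without cKO 0 h replicate 2 it was 0.08.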

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

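The interaction tests of the gene lists and LPS-responsive sets were planned before the data were examined, and the test of GC content and length, the use of the authors' fold changes and the medians of induced genes before LPS were chosen after the data were seen.

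The LPS change of 4 gene lists differed between the genotypes by the camera test of the interaction, with a preset correlation. The adjusted p was 1.1e-07 for mitochondrially encoded transcripts (median -0.65), 0.00452 for cholesterol synthesis (median 0.20), 0.0213 for interferon-stimulated genes (median -0.23) and 0.0271 for inflammatory cytokines (median -0.29). With an estimated correlation the adjusted p-values were 0.545, 0.81, 0.924 and 0.773, and limma called 0 genes of these lists, with 6, 1, 0 and 2 at an unadjusted p under 0.05. The cytokine list had an adjusted p of 0.755 without WT 0 h replicate 2, 0.146 without WT LPS replicate 1, 0.241 without cKO 0 h replicate 2 and 0.129 without cKO LPS replicate 1. Cholesterol synthesis had 0.743 without WT 0 h replicate 2 and 0.0595 without WT LPS replicate 2. Interferon-stimulated genes had 0.152 without WT 0 h replicate 2, 0.258 without WT LPS replicate 1 and 0.0646 without cKO LPS replicate 1, and turned to the higher side without cKO 0 h replicate 2 (adjusted p = 0.012). The 1296 genes induced by LPS had a smaller LPS change in cKO by limma's camera test (adjusted p = 5.48e-07), and the 820 repressed genes a less negative one (adjusted p = 6.23e-05). With an estimated correlation the adjusted p-values were 0.0727 and 0.0496. Under quantile normalization the median interaction of the induced genes, chosen again there, was -0.11.

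LPS-induced genes were lower in cKO after LPS, with a median of -0.32 over 1296 genes, and before LPS their median was -0.12 (-0.063 without cKO 0 h replicate 1 and -0.19 without cKO 0 h replicate 2). Neither a bias by GC content or transcript length nor a single library accounts for the whole of the difference after LPS, since the median was -0.306 after each sample was corrected for both properties, and -0.269 was the value nearest 0 with a library left out. The authors' deposited log2 fold changes had a median of -0.328 over the same genes. They come from the same libraries, and the transformation pulls values toward a gene's mean, so the fall could hardly have been absent there. That check therefore decides little about the transformation, and it does not bear on scaling between samples. The test that bears on a weaker induction is the interaction, with a median of -0.20 (adjusted p = 5.48e-07, and adjusted p = 0.0727 with an estimated correlation), which was -0.12 over the same genes without cKO 0 h replicate 2. A weaker induction in the absence of PTIP and a lower level at both times stay open as hypotheses, beside differences between mice or cultures, which 2 samples per group cannot separate from genotype.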

How the results depend on the processing

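The corrections for GC content and length and the counts from the authors' deposited table were chosen after seeing the data; the other settings were planned. Where a count moved, the cause was not tested, except that a size threshold removes calls, a fit of 2 groups has fewer samples, and leaving out a library leaves a lone sample that is assumed to vary like the other groups. The depth is unknown, so its limit on low genes cannot be given.

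With an absolute log2 change of at least 1 the calls numbered 2347 for LPS in WT, 1973 for LPS in cKO, 2116 for the averaged LPS effect, 238 for cKO after LPS and 227 for the averaged cKO effect. With no filter on low values they were 114 for cKO at 0 h, 208 for cKO after LPS, 359 for the averaged cKO effect and 10 for the interaction. Without a variance trend they were 9 for cKO at 0 h and 301 for cKO after LPS. Quantile normalization gave 235 for cKO after LPS, and the fit of only the 2 groups compared gave 0 for cKO at 0 h. The authors' deposited table gave 176 for cKO at 0 h. With a replicate block the counts were 72 for cKO at 0 h and 804 for cKO after LPS, and the block with the GC and length correction gave 79 for cKO at 0 h. Deviations of same-numbered samples correlated between -0.04 and 0.31 over the 6 pairs of groups, with 0.22 within WT and 0.31 within cKO. The labels do not say that a number marks a mouse or culture, so a shared one stays open and no pairing was assumed. Of the 55 list calls 0 held with an estimated correlation, and 30 held with fry's directional test, which asks whether a list moves at all and not whether it differs from other genes. The 25 lost with fry include all 4 for the interaction (adjusted p = 0.249 to 0.755). For cKO at 0 h they include cytokines (adjusted p = 0.14), chemokines and NF-kB targets (adjusted p = 0.087 each) and immediate early genes (adjusted p = 0.109). Also lost there were antigen presentation, alternative activation, Toll-like receptor, unfolded protein response, negative feedback and interferon-stimulated lists (adjusted p = 0.0622 to 0.741). For cKO after LPS, NF-kB targets, macrophage identity, immediate early and alternative activation genes were lost (adjusted p = 0.062 to 0.155). So were Toll-like receptor, mitochondrially encoded, negative feedback and interferon-stimulated genes (adjusted p = 0.177 to 0.389). Among all 170 tests fry called 37 directional and 104 mixed changes.

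Leaving out each library gave 3661 to 4770 calls for LPS in WT, 2684 to 4468 for LPS in cKO, 2 to 128 for cKO at 0 h, 0 to 582 for cKO after LPS, 0 for the interaction, 5294 to 5924 for the averaged LPS effect, 109 to 775 for the averaged cKO effect and 48 to 69 for gene lists. The median interaction ranged from -0.25 to -0.10 for induced and from 0.08 to 0.18 for repressed genes, and kept its sign in each alternative run for these sets. Each of these runs chose the sets again. The camera p-values of these alternatives were not adjusted and went up to 0.0141 for induced and 0.0454 for repressed genes, both without cKO 0 h replicate 2; with an estimated correlation the adjusted p-values were 0.0727 and 0.0496. Other filters and variance models were not run for these sets.

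Of 298 called gene results, quantile normalization turned 1, Cox7a2 under LPS in WT (-0.011), and ended 42 calls, while 89 were lost with no filter on low values and 36 without a variance trend. The other reversals among genes were in values that had not passed. Under quantile normalization they were Paxip1 under LPS in cKO (-0.24), Rif1 in cKO at 0 h (-0.005) and Ccl5 in cKO after LPS (0.10). Under the GC and length correction, with and without the replicate block, they were Dpy30 (0.14) and Kmt2d (-0.18) in cKO after LPS. With a library left out, the ranges for cKO at 0 h were -1.75 to 0.68 for Ccl5, -2.07 to 0.058 for Cxcl10, -0.40 to 0.52 for Il10, -0.28 to 0.026 for Kmt2d, -1.46 to 0.14 for Nos2, -0.10 to 0.17 for Rif1 and -0.10 to 0.025 for Wdr5. For cKO after LPS they were -0.26 to 0.39 for Arg1, -0.15 to 0.43 for Ash2l, -0.33 to 0.19 for Dpy30, -0.27 to 0.34 for Kmt2d and -0.34 to 0.11 for Ncoa6. The adjusted p of the interferon-stimulated list ranged from 1.93e-23 to 0.152 in cKO at 0 h and from 7.24e-17 to 0.258 for the interaction, and it turned direction in each.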

Other observations

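The tests of Lyz1, of heat shock genes and of single WT libraries on immediate early genes, and the correction for GC content and length, were chosen after the result was seen.

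In cKO after LPS, adhesion and matrix genes fell in 6 of 30 (8 lower and 1 higher adjusted over the list alone), led by Mmp13 and Vcam1, with an adjusted p of 0.0299 (adjusted p = 0.398 with an estimated correlation, 0.0699 without WT LPS replicate 1, and 0.0671 with a minimum mean rlog of 5). Lysosome genes did not pass as a list (adjusted p = 0.347), with 3 of 36 called lower (5 adjusted over the list alone), among them Ctsl (-1.16) and Lamp2 (-0.85), a protease and a membrane protein of that organelle, and the channel gene Mcoln1 (1.45) called higher (2 adjusted over the list alone). Nor did p53 targets (adjusted p = 0.432), of which Pmaip1 (-1.35) and Mdm2 (-0.75) were called, 2 of 25 (7 lower and 2 higher adjusted over the list alone). The integrin gene Itgam fell by 1.11 and Hif1a by 0.73. Quantile normalization ended the calls of Ctsl (adjusted p = 0.0951), Lamp2 (adjusted p = 0.0869), Mdm2 (adjusted p = 0.0654) and Hif1a (adjusted p = 0.119). Mitochondrially encoded transcripts were lower as a list (median -0.45, adjusted p = 0.000392, 0 of 15 genes called by limma, 7 at an unadjusted p under 0.05 and 4 lower adjusted over the list alone), and that adjusted p was 0.773 with an estimated correlation and 0.064 after the GC and length correction.

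Lyz1 was higher and Lyz2 lower in cKO. Lyz2, singled out after its values were seen, lies from 117277331 to 117282321 on chromosome 10, and was lower by 0.92 averaged over times (adjusted p = 0.0442). If a constant share of Lyz2 reads were counted to Lyz1, the difference between the genes would be alike in both genotypes, but it differed by 3.94 (SE 0.14). Of 32 other tested genes within 5 Mb of Lyz1, 2 were called for the averaged cKO effect (6.25%, against 7% elsewhere, Fisher's exact p = 1, two-sided), so a linked region that differs between the genotypes cannot be told apart from none, with an upper 95% limit of 20.8%. The labels do not name the Cre driver, and an altered Lyz2 allele in cKO mice may be a candidate explanation that was not tested.

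Immediate early genes were lower in cKO at 0 h, where their median rlog was 10.27 and 9.66 in WT and 9.52 and 9.12 in cKO. A single high WT library does not account for the whole difference: without either WT library the median difference nearer 0 was -0.559, against -0.88 with both, so WT 0 h replicate 1 sets its size in part. Stress in the WT cultures cannot be told apart from an effect of genotype, because heat shock genes had a median near 0 with members going both ways (adjusted p = 0.642). Genotype and handling stay open, and replicate 1 was also above replicate 2 after LPS, at 9.56 and 8.70 in WT and at 8.38 and 7.79 in cKO.

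Over the 34 splits of the 8 samples into 4 and 4 that could be fitted beside the other factor, the real split was the 1 that called as many genes for either factor. It called 6220 genes for LPS, where the highest other split called 0, and 798 for cKO, where the highest other split called 1. The other cKO split with a call set replicate 1 against replicate 2 in every group. A share of 1 in 34 is the smallest these splits can give, and in the other splits the real difference adds to the spread and lowers their counts. The splits also take the 8 libraries as exchangeable, which a mouse or culture shared between times would break. The averaged cKO count of 810 in the model with 4 group means was 109 without cKO LPS replicate 2.

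In cKO at 0 h, 220 genes were over 1 log2 unit higher in replicate 2 than in replicate 1 and 20 were lower by more than that, against 84 and 117 in WT at 0 h. Tysnd1, for example, was at 5.95 and 7.73 in cKO at 0 h, and at 4.54 and 4.67 in WT. The 220 genes had a median difference between cKO and WT after LPS of 0.92, a median GC content of 50.3% (49% in the rest) and a median transcript length of 2560 nt (3180 nt in the rest). Across genes, the difference between cKO and WT after LPS correlated with GC content at a Spearman's rho of 0.299, against 0.0343 at 0 h. For the interaction rho was 0.303, with -0.124 for LPS in WT and 0.00772 for LPS in cKO. After the GC and length correction 298 of 453 calls for cKO after LPS with a GC value were kept. The median interaction of the induced genes was -0.195 before that correction and -0.19 after it.

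Marker genes from lists of other cell types with fewer than 5 tested members gave these values in cKO against WT after LPS, none past the threshold. They were -0.19 for Lck and -0.65 for Il7r (T cells), -0.21 for Tfrc and 0.31 for Car2 (erythroid cells), and -0.32 for Ly6a and -0.31 for Kit (progenitors). For stromal and endothelial cells they were -0.46 for Kdr, -0.44 for Acta2, -0.37 for Pdgfrb and -0.45 for Pecam1.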
